A study of Mus musculus with 3 samples.

How the data were processed

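Translating ribosome affinity purification (TRAP) isolates the messages carried by polysomes that hold an EGFP-tagged ribosomal protein L10a made in a chosen set of cells. The Slc17a6-TRAP mouse line JX883 carries the tagged protein under control of Slc17a6, which encodes the vesicular glutamate transporter VGLUT2. Per the labels' protocols, prefrontal cortex of adult mice was homogenized, tagged polysomes were immunopurified with anti-EGFP antibodies on magnetic beads, and the RNA of the immunopurified fraction was sequenced. There were 3 immunopurified libraries, each from 3 mice according to the labels, and all 3 form 1 group. No input RNA or second group was analysed here, so a level is the abundance of a message in the immunopurified RNA and not its enrichment over the tissue. P-values take a library as the unit. Those of the goodness of fit described below set a gene's variation between libraries against that of genes of like abundance. Those of the sign-flip contrasts are 0.25 for any contrast in 1 direction in 3 of 3 libraries, whatever its spread.

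The authors deposited raw counts per gene symbol for each library, as whole numbers followed by the summary lines that HTSeq writes. STAR 2.0.0e, HTSeq and the mouse build mm10 are named in the submitters' processing notes, without their settings. The gene annotation and the use of strand in counting are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene may not have been told apart. The lines that name no gene held 27.8% ± 0.56 (SD, n = 3) of all counts, of which 13.3% were reads placed at more than 1 position, 11.8% reads outside genes and 2.76% reads shared by genes. These lines were left out of library totals and tests. Members of families with near-identical copies, such as ribosomal proteins, are uncertain because reads placed at several positions were not counted.

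Each table held 32531 gene symbols, of which 18377 had a count in any library and 0 were mitochondrially encoded. The list of mitochondrially encoded messages and the alternatives that leave them out therefore gave no value. CPM, the gene's counts scaled to a common library total, were computed over the total of named genes in each library, and log2 values used a pseudocount of 0.5 CPM. A count of 0 allows up to 3 counts, equal to 0.238, 0.335 and 0.237 CPM in replicates 1, 2 and 3, for counting error only, since reads without molecular identifiers are not independent molecules. Positions, identifiers, exon lengths and overlaps came from GENCODE M21 on mm10, matched by symbol. A match was found for 87.1% of symbols with a count and for 94.1% of genes at 1 CPM or more in every library. TPM values, which also account for transcript length, were derived from the deposited counts and the lengths of merged exons as an alternative.

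Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The 36 lists covered vesicular transporters, cell classes, neighbouring regions, cortical layers, receptors and peptides, and the state of the RNA or the tissue. The rule named all 6 vesicular transporters, the 2 highest and the lowest member of each list by mean CPM, all members of receptor lists of 5 or fewer, the 10 highest genes, and up to 10 varying genes with the smallest p and a mean of at least 5 CPM. Some genes that this rule names are not reported here. Other genes in the text were chosen after their values were seen. A list was summarised as the mean log2 CPM of its members in each library. Contrasts within a library were tested with an exact two-sided sign-flip permutation test, whose smallest p with 3 libraries is 0.25, so no contrast of this kind could pass 0.05. The range of a list over the libraries was set against 10000 random lists of the same size, drawn gene by gene from the 50 ranks on either side, as a description of these libraries.

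Genes that varied between libraries were called with the goodness of fit of an intercept-only negative binomial model in edgeR 4.0.16, with TMM normalization and the trended dispersion. The deviance was compared with a chi-square distribution of 2 degrees of freedom, with Benjamini-Hochberg adjustment at 0.05, for genes with at least 10 counts in at least 1 library. Alternatives were a limma 3.58.1 variance test, DESeq2 1.42.0 size factors, other count minimums, a common dispersion, a stricter threshold and each replicate left out. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Totals without the ribosomal RNA precursor gene Rn45s were an alternative chosen after seeing the data.

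The tests of varying genes were tested on simulated data with 200 of the real genes moved in 1 library, and the list ranges on random lists of 10 genes. Simulated counts were drawn at the trended dispersion that the edgeR test assumes. Their false calls therefore do not cover real genes that scatter around the trend. The moved genes averaged at least 50 counts, so recovery at lower counts was not tested. The sign-flip contrasts were not simulated. For genes varying between libraries, edgeR recovered 22.5% of genes moved 2-fold, with 6 false calls among 14177 genes, and 77% of genes moved 4-fold, with 11 false calls among 14192 genes. The limma test recovered 29.5% and 77%. Its first version, with prior degrees of freedom estimated for each gene, recovered 37 of 200 genes at 2-fold and 0 of 200 at 4-fold. It was replaced by 1 common prior because of that failure, after its 13 calls in the 3 libraries had been seen. The replacement called 38. For list ranges, 6 of 100 unshifted lists and 100 of 100 lists shifted by 1 log2 unit in a library reached the 95th percentile. The unshifted lists were random genes set against random genes, so their share followed from the percentile itself. It does not cover lists whose members vary together. Members averaged at least 5 CPM, and smaller shifts or lists with lower members were not tested.

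One grouping in the closing section was also revised after its result was seen. Lists lower in replicate 1 were first tested as a group of 4 that included the GABAergic markers. That list was then dropped because its level in replicate 1 was close to that in replicate 3, which left a group of 3. Both results are given.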

Results

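RNA immunopurified with tagged ribosomes was profiled from the prefrontal cortex of adult Slc17a6-TRAP JX883 mice in 3 libraries, each from a pool of 3 mice. No input or untagged control was analysed, so RNA carried along without a tagged ribosome could not be told apart. Totals over named genes were 12592174, 8964137 and 12648577 counts in replicates 1, 2 and 3. At 1 CPM or more in every library, 12321 genes were expressed, and 2148 of them averaged 100 CPM or more. The ribosomal RNA precursor gene Rn45s was highest at 72012 ± 9016 CPM (SD, n = 3), or 7.20% ± 0.90 of counts. Reads of the precursor and of mature ribosomal RNA were not told apart. Rn45s was followed by Snap25, a SNARE protein of synaptic vesicle release, at 24671 ± 987 CPM, and by the neuronal calcium sensor Vsnl1 at 6748 ± 270 CPM. Ywhaz (5584 CPM), Lars2 (4850 CPM), Ndrg4 (4128 CPM), the microtubule protein gene Map1b (3781 CPM), Calm2 (3711 CPM) and Gapdh (3657 CPM) were also among the 10 highest genes, which held 13.5% ± 0.76 of counts.

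The replicates were compared before they were averaged. Across 18377 genes, which are not independent replicates, Pearson's r of log2 CPM was 0.975 for replicates 1 and 2, 0.976 for 1 and 3, and 0.971 for 2 and 3, and Spearman's rho was 0.966, 0.967 and 0.963. By the labels the libraries are separate samples. In a check for a library deposited more than once, counts of no pair agreed within sampling noise, with chi-square values of 12.5, 17.4 and 13.7 per degree of freedom. The biological coefficient of variation in edgeR was 29.8%.

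The first question was how the message of the driver gene compared with those of other vesicular transmitter transporters. Slc17a6 (ENSMUSG00000030500.6, mm10 chromosome 7, 51622006 to 51671119) stood at 831 ± 97.4 CPM (SD, n = 3), rank 108 of all genes. Slc17a7, which encodes the vesicular glutamate transporter VGLUT1 (chromosome 7, 45163949 to 45176142), stood at 307 ± 17.3 CPM. Slc32a1, the vesicular transporter of GABA and glycine (chromosome 2, 158610767 to 158615748), was at 31.0 ± 8.89 CPM, and the monoamine transporter Slc18a2 at 5.47 ± 1.12 CPM. The third vesicular glutamate transporter gene, Slc17a8, had 1.67, 5.80 and 1.66 CPM in replicates 1, 2 and 3. The acetylcholine transporter Slc18a3 had 0 counts in replicates 1 and 2 and 2.69 CPM in replicate 3.

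Slc17a6 exceeded Slc17a7 by 1.43 ± 0.25 on the log2 scale, or 2.70-fold, in 3 of 3 libraries (exact sign-flip permutation p = 0.25, adjusted p = 0.25 over 5 contrasts). It exceeded Slc32a1 by 4.75 ± 0.55, or 27.0-fold, and Slc18a2 by 7.13 ± 0.25, each in 3 of 3 libraries with the same p. The fold over Slc32a1 was 14.1 in TPM, and 24.9% of the exonic bases of Slc32a1 were shared with another annotated gene. Whether any transgene sequence added reads to Slc17a6 or to Rpl10a, the gene of the tagged protein, was not tested.

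**Figure D1:**
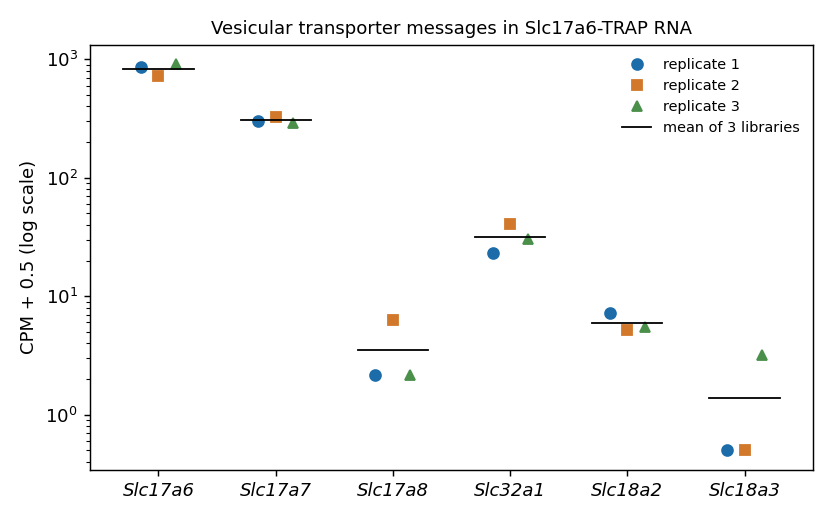
CPM + 0.5 of the 6 vesicular transporter genes on a log axis, with a symbol for each of the 3 libraries and a line at the mean. Slc17a6 averaged 831 CPM and Slc17a7 307 CPM, and Slc17a6 was the higher of the pair in 3 of 3 libraries.

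The second comparison set markers of excitatory cortical neurons against those of other cell classes. The glutamatergic neuron list was led by Camk2a, a calcium-dependent kinase subunit of excitatory neurons, at 2884 ± 265 CPM, and by the synaptic vesicle gene Sv2b at 691 ± 63.1 CPM. Its lowest member was the cortical transcription factor gene Emx1 at 3.00 ± 1.55 CPM. All 10 members reached 1 CPM in every library. Members of the GABAergic neuron list were also detected, though their cell of origin was not tested. All 14 of 14 reached 1 CPM in every library, led by the GABA-synthesizing enzyme gene Gad2 at 626 ± 45.2 CPM. The peptide gene Cck followed at 428 ± 53.4 CPM, and Vip was lowest at 3.42 ± 2.51 CPM. The glutamatergic list exceeded the GABAergic list by 1.93 ± 0.19 log2 units, or 3.80-fold, in 3 of 3 libraries. Of the 14 GABAergic members, 6 were also on another list.

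Among glial lists, the astrocyte list was led by the glutamate transporter gene Slc1a2 at 985 ± 70.0 CPM and by Aldoc at 348 ± 60.5 CPM, and its lowest member was Aldh1l1 at 5.68 ± 2.20 CPM. It lay below the glutamatergic list by 4.01-fold (SD 0.27 log2 units). The oligodendrocyte list lay 2.48 ± 0.17 units below, with the myelin gene Mbp at 175 ± 26.4 CPM and with Opalin at 0.969 ± 0.583 CPM. The oligodendrocyte precursor list lay 3.56 ± 0.23 units below, with Lhfpl3 at 38.2 ± 8.14 CPM, Olig1 at 20.8 ± 3.17 CPM and Cspg4 at 4.87 ± 0.888 CPM. Microglia markers lay 5.20 ± 0.11 units below, led by Csf1r at 13 ± 3.92 CPM and Ctss at 7.51 ± 2.25 CPM, while the complement gene C1qa had 0 counts.

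Vascular, ventricular and blood markers were lowest in the main summary. The endothelial list lay 6.75 ± 0.19 log2 units below the glutamatergic list, with Itm2a at 5.56 ± 0.594 CPM, Flt1 at 2.40 ± 0.291 CPM and the tight junction gene Cldn5 at 0.0529 ± 0.0917 CPM. The mural and meningeal list lay 6.23 ± 0.08 units below, with Rgs5 at 17.3 ± 2.58 CPM, Acta2 at 4.20 ± 0.566 CPM and Slc47a1 at 0 counts. The ependymal and choroid plexus list lay 6.32 ± 0.31 units below, with Prlr at 22.6 ± 7.69 CPM, Foxj1 at 6.11 ± 2.84 CPM and 0 counts of Folr1, Kcne2 and Tmem212. The blood cell list, of which 5 of 7 members were in the tables, lay 7.03 ± 0.26 units below, with the haemoglobin gene Hbb-bs at 1.42 ± 0.566 CPM, Ptprc at 0.786 ± 1.17 CPM and Lyz2 at 0.301 ± 0.228 CPM.

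Neighbouring regions were covered by 3 lists. Striatal neuron markers lay 2.07 ± 0.31 log2 units below the glutamatergic list, led by the enkephalin precursor gene Penk at 201 ± 51.7 CPM and the phosphodiesterase gene Pde10a at 171 ± 42.7 CPM, with Adora2a at 6.65 ± 4.99 CPM. Thalamic neuron markers lay 3.40 ± 0.24 units below, led by Zfhx3 at 144 ± 15.3 CPM and Ntng1 at 99.4 ± 11.1 CPM, with 0 counts of the thalamic transcription factor gene Gbx2. Olfactory bulb markers lay 4.74 ± 0.65 units below, with Cdhr1 at 76.6 ± 52.3 CPM, Trh at 28.7 ± 12.4 CPM and Ppm1j at 0.0794 ± 0.138 CPM.

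Each of these 12 contrasts had the same direction in 3 of 3 libraries, with an exact sign-flip permutation p of 0.25 and an adjusted p of 0.25. Their sizes depended on how a list was summarised: with the median over members the GABAergic, astrocyte, oligodendrocyte, thalamic, striatal and ependymal lists lay 2.76, 3.14, 1.87, 4.12, 2.72 and 7.26 units below. In TPM the microglia and blood lists lay 4.18 and 6.33 units below. Lengths were assigned only to genes with a count, so members with 0 counts dropped out of TPM. The microglia value therefore left out C1qa, which by itself raised that list. The ependymal value was void because 66.7% of its members had a length, the others being its members with 0 counts. With a pseudocount of 0.1 CPM the endothelial, mural, ependymal and blood lists were 7.63, 6.99, 7.42 and 7.93 units below. With members averaging under 1 CPM left out, the endothelial, mural, ependymal and olfactory lists lay 5.54, 5.10, 4.58 and 3.73 units below. The microglia list then lay 4.66 units below, so the ependymal list was no longer the lower of those 2.

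**Figure D2:**
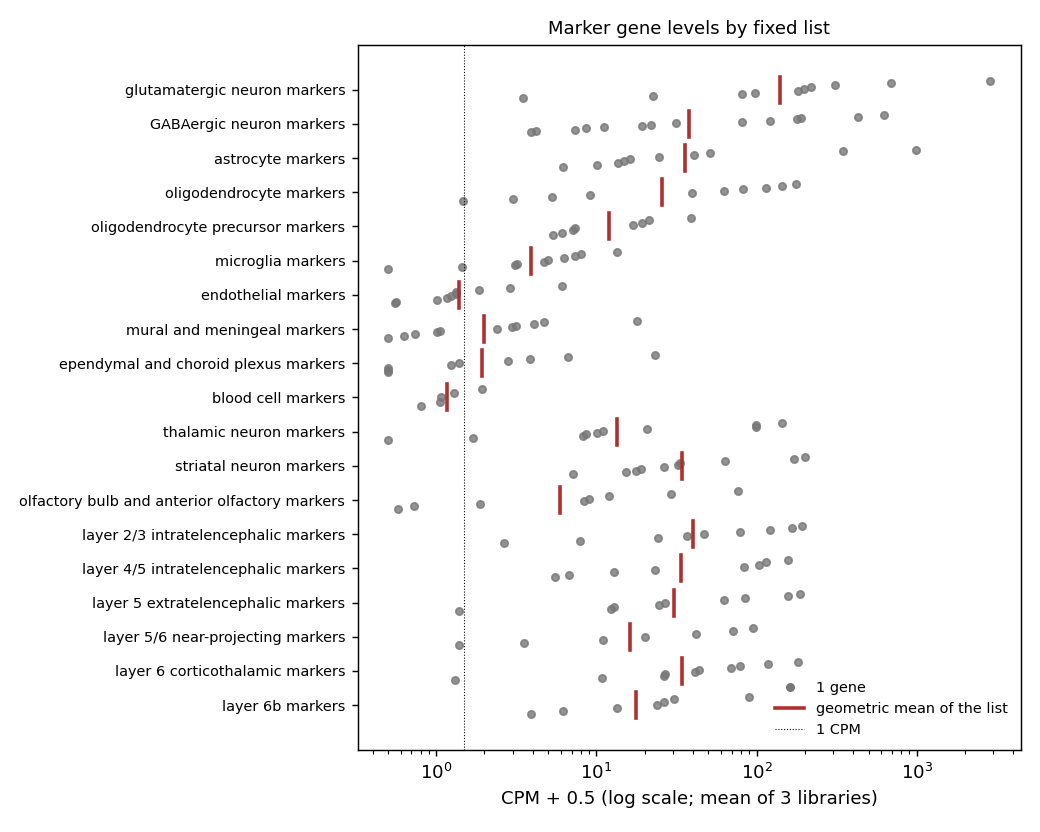
CPM + 0.5 of each marker gene as the mean of 3 libraries on a log axis, by fixed list of cell class, neighbouring region or cortical layer; grey points are genes, red bars geometric means and the dotted line 1 CPM. Camk2a at 2884 CPM was the highest gene of the glutamatergic list, and Cldn5 at 0.0529 CPM the lowest of the endothelial list.

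The third comparison concerned cortical layers, each list being set against the mean of the 6 layer lists. Layer 2/3 intratelencephalic markers stood 0.54 ± 0.04 log2 units above that mean (SD, n = 3), led by Rasgrf2 at 192 ± 10.5 CPM and the transcription factor gene Cux1 at 165 ± 10.5 CPM, with Cdh24 at 2.15 ± 2.55 CPM. Layer 6 corticothalamic markers stood 0.34 ± 0.13 above, led by the corepressor gene Tle4 at 182 ± 10.7 CPM and Sema5a at 117 ± 6.42 CPM, with Ctxn3 at 0.810 ± 0.539 CPM. Layer 6b markers stood at -0.59 ± 0.05, with the nuclear receptor gene Nr4a2 at 88.7 ± 16.1 CPM, Ctgf at 29.9 ± 2.81 CPM and Svil at 3.42 ± 0.364 CPM. Layer 5/6 near-projecting markers stood at -0.74 ± 0.19, with Tshz2 at 94.4 ± 8.86 CPM, Cbln1 at 70.5 ± 25 CPM and Sla2 at 0.884 ± 0.336 CPM. Of the exonic bases of Tshz2, 67.5% were shared with other annotated genes.

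Layer 4/5 intratelencephalic markers stood 0.30 ± 0.21 above the mean, with Fezf2 at 156 ± 24.1 CPM, Etv1 at 113 ± 13.6 CPM and Scnn1a at 4.98 ± 4.02 CPM. Layer 5 extratelencephalic markers stood 0.15 ± 0.16 above it, in 2 of 3 libraries, with Ldb2 at 186 ± 27.3 CPM, Fezf2, which is on both lists, and Chrna2 at 0.894 ± 1.02 CPM. The exact sign-flip permutation p was 0.25 for 5 of the lists and 0.5 for the layer 5 extratelencephalic list (adjusted p = 0.3 and 0.5 over 6 contrasts). The order of the 4 upper lists depended on the members used. With genes on more than 1 list left out, the layer 5 extratelencephalic list was highest at 0.52 ± 0.10, followed by layer 6 corticothalamic (0.35), layer 2/3 (0.30) and layer 4/5 (-0.06). With members averaging under 1 CPM left out, layer 6 corticothalamic markers were highest at 0.59, followed by layer 5 extratelencephalic (0.45), layer 2/3 (0.26) and layer 4/5 (0.02). With the median over members the layer 5 extratelencephalic value became -0.20. In TPM the layer 2/3, layer 4/5 and layer 6b values were 0.34, 0.13 and -0.25. The layer 4/5 value was 0.18 without replicate 3, and the layer 5 extratelencephalic value 0.07 without replicate 1. The near-projecting and layer 6b lists were the lowest pair under all of these settings, and the layer 6b list was the lower of them when members were left out (-0.72 and -0.88).

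Receptors and peptides were described by level. Of 97 genes on 11 lists, 81 reached 1 CPM in every library. AMPA and kainate receptor subunits all did so (9 of 9), led by Gria2 at 555 ± 39.3 CPM and Gria3 at 415 ± 54.5 CPM, with Grik1 lowest at 7.53 ± 1.13 CPM. Among NMDA receptor subunits 6 of 7 did, with the obligatory subunit gene Grin1 at 247 ± 27.7 CPM, Grin2b at 120 ± 11.5 CPM and Grin3b at 0.105 ± 0.183 CPM. Among metabotropic glutamate receptors 7 of 8 did, with Grm5 at 117 ± 9.00 CPM and Grm6 at 0 counts. Among GABA-A receptor subunits 12 of 13 did, with Gabra6 at 0.0264 ± 0.0456 CPM.

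Among serotonin receptors 9 of 13 reached 1 CPM in every library, with Htr2c at 51 ± 4.91 CPM, Htr5a at 44.9 ± 12.9 CPM and Htr2b at 0.0264 ± 0.0456 CPM. Among dopamine receptors 3 of 5 did: Drd1 at 25.8 ± 2.64 CPM, Drd2 at 18.4 ± 2.72 CPM and Drd5 at 2.77 ± 1.23 CPM, while Drd3 was at 0.932 ± 1.05 CPM and Drd4 had 0 counts. For Drd5, 48.6% of exonic bases were shared with another annotated gene. Among adrenergic receptors 6 of 9 did, with Adra1a at 27.9 ± 5.98 CPM and Adra1d at 21.9 ± 3.58 CPM. Muscarinic receptors all did (5 of 5), at 84.1 ± 18.2 CPM for Chrm1, 16.8 ± 1.93 for Chrm3, 9.84 ± 2.02 for Chrm2, 7.80 ± 1.28 for Chrm4 and 4.11 ± 2.53 for Chrm5. Among nicotinic receptor subunits 6 of 9 did, with Chrna4 at 90.2 ± 8.89 CPM, Chrnb2 at 51.7 ± 7.4 CPM and Chrna6 at 0.264 ± 0.229 CPM. Opioid receptors all did (4 of 4), at 34.1 ± 2.92 CPM for the nociceptin receptor gene Oprl1, 26.8 ± 6.04 for Oprm1, 16.4 ± 4.17 for Oprd1 and 3.79 ± 1.24 for Oprk1. Among neuropeptides 14 of 15 did, led by Cck and Penk, with Cort at 0.238 ± 0.413 CPM.

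Lists on the state of the RNA and tissue were described in the same way. Immediate early genes, which neuronal activity induces, were led by Egr1 at 1180 ± 194 CPM and Egr3 at 620 ± 73.5 CPM, with Ier2 lowest at 1.03 ± 1.40 CPM. Of nuclear-retained noncoding RNAs, Malat1 stood at 1123 ± 173 CPM, Meg3 at 286 ± 24.6 CPM and Neat1 at 1.66 ± 1.39 CPM. Of the sex-linked messages, Ddx3y, on the Y chromosome, was at 19.3, 10.3 and 23.5 CPM in replicates 1, 2 and 3, and Xist, expressed from the inactive X, at 8.42, 12.4 and 1.98 CPM. Eif2s3y averaged 10.5 ± 4.66 CPM and Uty 2.51 ± 1.14 CPM. Among ribosomal protein genes, Rpl3 was at 315 ± 16.2 CPM, Rps3 at 170 ± 9.56 CPM, Rpl10a, which encodes the tagged protein, at 159 ± 3.79 CPM, and Rplp0 at 69.9 ± 2.34 CPM.

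Of 14774 genes tested, 36 varied between the 3 libraries beyond the trend in edgeR at an adjusted p of 0.05, against 1066 at an unadjusted p of 0.05. The limma variance test called 38, of which 23 were shared. With a common dispersion in place of the trend 1097 genes were called, of which 26 were among the 36, and at an adjusted p of 0.01 in edgeR 18 were called. Vars2, a mitochondrial valyl-tRNA synthetase gene, had 8.50, 4.80 and 93.1 CPM in replicates 1, 2 and 3 (adjusted p = 3.5e-27). Higher in replicate 2 were the glycosyltransferase gene Ext2 (35.5, 219 and 48.9 CPM), Mprip (168, 662 and 195 CPM), the centrosomal gene Cep135 (12.7, 99.95 and 15.7 CPM), Limch1 (28.6, 157 and 50.4 CPM) and Rab11fip4 (92.4, 245 and 80.6 CPM). Higher in replicate 1 were the nuclear pore gene Tpr (615, 199 and 175 CPM), the transcription factor gene Ebf3 (138, 64.7 and 31.2 CPM) and Zfp619 (21.9, 2.68 and 2.69 CPM). Cdhr1, a cadherin-related gene, was lower in replicate 3 (116, 95.9 and 17.3 CPM).

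Each of these 10 genes lost its call when the library that stood apart was left out, which was replicate 3 for Vars2 and Cdhr1, replicate 1 for Tpr, Ebf3 and Zfp619, and replicate 2 for the others. Rab11fip4 also lost its call with a common dispersion (adjusted p = 0.122 in edgeR). Without replicates 1, 2 and 3 in turn, 16, 16 and 21 genes were called, of which 15, 13 and 18 were among the 36.

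Of the genes on the fixed lists, Tcf7l2, Cdhr1, Egr2 and Nr4a1 were among the 36. Adjusted over the list alone, 5 olfactory bulb markers (Tbx21, Eomes, Cdhr1, Trh and Doc2g), 5 immediate early genes (Fosb, Junb, Egr2, Nr4a1 and Ier2) and 5 neuropeptides (Sst, Penk, Tac2, Adcyap1 and Trh) varied. So did 2 striatal markers (Penk and Pde10a), 2 sex-linked messages (Xist and Kdm5d) and 1 member in each of 8 lists, among them Slc18a3, Sst, Gfap, Ccdc153, Tcf7l2, Cbln1 and Xist. Adjusted over the list alone, the other 22 of 35 lists had 0 such members. No adjustment was made across the 35 lists. Adjusted over all genes, 3 lists had a call, against 13 when each list was adjusted alone.

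As groups, 10 of 35 lists had a range over the libraries at or above the 95th percentile of matched random lists, where 1.75 would be expected by chance. The lists were not independent, since 7 of 15 neuropeptides, 6 of 14 GABAergic markers and 4 of 10 striatal markers were also on another list. Shared members leave that expected number unchanged but alter its spread by chance, which was not estimated. The widest was the olfactory bulb list, with a range of 1.23 log2 units (100th percentile) and means of 2.88, 2.61 and 1.65 in replicates 1, 2 and 3. Immediate early genes ranged over 0.77 units (5.79, 5.48 and 5.02), striatal markers over 0.62 (4.73, 5.07 and 5.35), neuropeptides over 0.54 (4.07, 4.28 and 4.61) and astrocyte markers over 0.54 (4.84, 5.13 and 5.38). Nuclear-retained noncoding RNAs, layer 5 extratelencephalic, thalamic, layer 4/5 intratelencephalic and GABAergic lists ranged over 0.55, 0.46, 0.46, 0.44 and 0.33 units. The nuclear-retained list was lowest in replicate 3 (4.99, 5.24 and 4.69 in replicates 1, 2 and 3). Its members were mixed, since Malat1 and Meg3 had their highest levels in replicate 3, and Neat1 and Xist their lowest. With the median over members 4 lists reached that percentile, and the striatal list (91.0), neuropeptides (69.0), thalamic markers (84.3), layer 4/5 (41.1), layer 5 extratelencephalic (90.4) and nuclear-retained RNAs (8.25) did not. With a pseudocount of 0.1 CPM the thalamic (93.5) and layer 5 extratelencephalic (92.2) lists fell below it, and with 1 CPM the GABAergic list (94.9). Leaving out a library took the range below it for the olfactory list (81.4th percentile without replicate 3), astrocyte markers (91.5 without replicate 1), neuropeptides (83.5 without replicate 3), thalamic markers (10.7 without replicate 1) and the GABAergic list (21.3 without replicate 2). It also did so for layer 4/5 (71.7 without replicate 2 and 87.8 without replicate 3), layer 5 extratelencephalic (73.4 without replicate 1 and 90.6 without replicate 2) and the nuclear-retained RNAs (81.9 without replicate 2 and 82.8 without replicate 3).

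**Figure D3:**
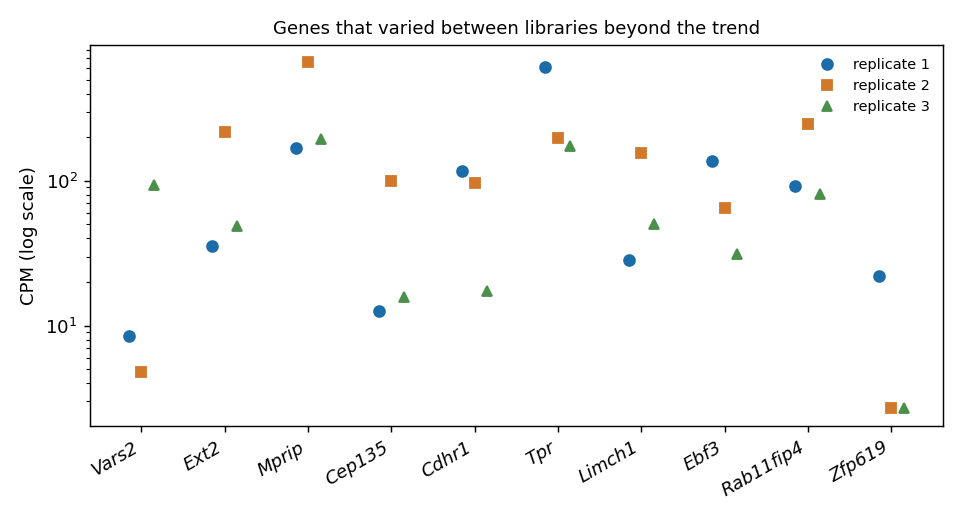
CPM per library on a log axis of the 10 named genes that varied between libraries, with a symbol for each replicate. Vars2 reached 93.1 CPM in replicate 3 against 8.50 and 4.80 CPM in the others, and Cdhr1 was at 17.3 CPM in replicate 3 against 116 and 95.9 CPM.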

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

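Totals without Rn45s were the alternative chosen after seeing the data. Contrasts of transporters kept their direction in 35 of 35 alternative values and those of cell class and region lists in 119 of 119. Layer contrasts did so in 58, and 2 reversed: layer 4/5 intratelencephalic markers (-0.059 with genes on more than 1 list left out) and layer 5 extratelencephalic markers (-0.20 with the median over members). Leaving out a library could not reverse a contrast with the same direction in 3 of 3 libraries. This held for every contrast but that of layer 5 extratelencephalic markers. For the transporters, a changed pseudocount or totals without Rn45s could not reverse a ratio either, so only TPM tested their direction. Totals without Rn45s rescaled all genes of a library alike, so they hardly tested the direction of list contrasts. The 119 values include that of the ependymal list in TPM, which was void as stated above. Expressed genes stayed within 1.5 times in 11 of 11. Mean replicate correlation was 0.962 for genes with at least 10 counts, 0.953 and 0.980 with pseudocounts of 0.1 and 1 CPM, and 0.971 to 0.976 with a replicate left out. Varying genes numbered 1097 with a common dispersion, 18 at an adjusted p of 0.01, and 16 to 21 with a replicate left out, which leaves fewer samples. Lists ranging at or above the 95th percentile numbered 4 with the median over members, and 20 of the 70 alternative values for single lists fell below it. The share of the 10 highest genes was 9.76% over all counts, by construction of the larger denominator. For the reversals, the dispersion and the median the cause was not tested. Alternatives without mitochondrially encoded messages gave no value, as the tables held 0 such genes. Depth limits genes near the floor of 3 counts. No paired analysis was possible because there was only 1 group.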

Other observations

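Families of excitability and release genes outside the fixed lists were chosen after the data had been seen, and are given as levels. Of 9 voltage-gated sodium channel alpha subunits, 6 reached 1 CPM in every library, led by Scn8a at 594 ± 16.8 CPM (SD, n = 3), Scn2a1 at 275 ± 7.21 CPM and Scn1a at 232 ± 26.4 CPM, while the muscle channel gene Scn4a was at 0.0265 ± 0.0458 CPM. Of 10 calcium channel alpha-1 subunits 8 did, with Cacna1e at 284 ± 38.4 CPM and Cacna1b at 115 ± 17.7 CPM. All 14 synaptotagmins examined, calcium sensors and related vesicle proteins that are not the whole family, reached 1 CPM in every library, led by Syt1 at 1204 ± 26.6 CPM, Syt11 at 548 ± 12.7 CPM and Syt4 at 319 ± 32.2 CPM.

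Of 18 other modulator receptors, 16 reached 1 CPM in every library. The GABA-B receptor genes Gabbr1 and Gabbr2 were at 334 ± 21.2 and 207 ± 29.7 CPM, the adenosine receptor gene Adora1 at 163 ± 15.1 CPM and the cannabinoid receptor gene Cnr1 at 107 ± 14.8 CPM. The oxytocin receptor gene Oxtr was at 11 ± 3.04 CPM and the vasopressin receptor gene Avpr1a at 0.952 ± 0.343 CPM. Of 8 neurotrophin and growth factor receptors 7 did, with Ntrk2, the BDNF receptor gene, at 470.5 ± 18.3 CPM and Ntrk3 at 59.8 ± 4.65 CPM.

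The 3 patterns below were noticed in the data. The tests chosen only after the result was seen were those of depth for Cdhr1, of other cell types and of the group of 3 lists for replicate 1, of the shallowest library for varying genes, and all 3 tests of genes with a higher level in 1 library. No biological explanation was tested, since the design has 1 group.

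The olfactory bulb markers Cdhr1, Eomes, Doc2g and Tbx21 had their lowest level in replicate 3, whereas Trh was at 15.5, 30.6 and 40.0 CPM in replicates 1, 2 and 3. Library depth was argued against by the near-equal totals of replicates 1 and 3 (ratio 0.996), between which Cdhr1, picked for its variation, differed 6.72-fold. Olfactory bulb tissue carried along in different amounts is a candidate explanation: a further list of mitral and tufted cell markers, written before its test, lay at the 99.9th percentile of matched lists for a lower level in replicate 3. Its mean shift was 0.63 log2 units (SD 0.84), with 5 of 8 members in that direction. The largest shift, 1.72, was that of Ms4a15 at 1.83, 0.669 and 0 CPM in replicates 1, 2 and 3, near the floor. Reln was at 121, 99.6 and 82.6 CPM and Spp1 at 12.5, 11.7 and 4.03 CPM. Lhx5 (-0.41), Nmb (-0.10) and Barhl2 (27.0, 37.7 and 34.1 CPM) went the other way. Cortex also expresses Reln, so the source of these messages stays open.

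Astrocyte, striatal neuron and neuropeptide lists were lower in replicate 1 than the mean of replicates 2 and 3, by 0.41, 0.48 and 0.38 log2 units. Each list rose stepwise over replicates 1, 2 and 3: astrocyte 4.84, 5.13 and 5.38, striatal 4.73, 5.07 and 5.35, neuropeptides 4.07, 4.28 and 4.61. Replicate 1 was therefore not alone in standing apart. The tests below set it against the mean of the others and do not separate the steps. With the median over members the ranges of the striatal list and neuropeptides fell to the 91.0th and 69.0th percentiles. The neuropeptide range stood at the 98.9th percentile without replicate 1 and at the 83.5th without replicate 3. Over 13569 genes, the shift between replicate 1 and the mean of the others had only a weak trend with gene length (Spearman's rho -0.027) and GC content (0.15). Removing the trend with gene length and GC content left the shift of the 4 lists first grouped, GABAergic markers included, at 0.35 (0.35 before), and that of the 3 lists chosen afterwards at 0.47 (0.47 before), which argues against this trend as the whole cause for either grouping. The GABAergic list shifted by 0.13 (92.1st percentile), so the larger value of the 3 lists reflects that choice. More RNA of other cells in replicates 2 and 3 cannot be told apart: 21 markers of 4 other cell types had a median shift of -0.078 (bootstrap interval -0.22 to 0.80), while their mean lay at the 98.1st percentile, and median and mean pointed in different directions. Of those cell types the ependymal list shifted by 0.75 (99.3rd percentile), endothelial by 0.32, microglia by 0.18 and mural by -0.17, and of other lists oligodendrocyte precursor by 0.38, thalamic by 0.45 and immediate early genes by -0.54.

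Of the 36 genes that varied, 22 stood apart by a higher level in 1 library, at least 3-fold above the lowest library, such as Vars2, Ext2 and Cep135: 5 in replicate 1, 13 in replicate 2 and 4 in replicate 3. Exons shared with other genes were argued against as the main cause, because 10% of these genes with an annotation (2 of 20, exact binomial interval 1.23 to 31.7) had over 20% of exonic bases shared, as had 12.9% of all varying genes (4 of 31, interval 3.63 to 29.8) and 7.24% of all genes tested. The shallowest library, replicate 2, was argued against as the whole cause, since the 9 of the 22 genes that stood higher in replicate 1 or 3 were called without it, as were 13 of the 36. The other 13 of the 22 also had more raw counts in replicate 2 than in either other library. Choosing them by fold already fixes at least 2.13-fold more raw counts than in the lowest library, so the order of counts decides nothing. Against the nearer library all 13, which were picked for their variation, exceeded counting noise (largest exact binomial p = 1.9e-14). This argues against counting noise at the lower depth as their cause, as far as reads are independent. Uneven amplification of a few molecules was not tested and stays open.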
